A study of Phaeodactylum tricornutum with 6 samples.

How the data were processed

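RNA was taken from 6 samples of Phaeodactylum tricornutum, 3 control and 3 given tunicamycin. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. The protocol also mentions a lower dose, which was not analysed here. Per the submitters' processing notes, CASAVA 1.7 and Bowtie 0.12.2 were used with the builds mm10 and GRCm38. Those are mouse builds and do not go with the diatom gene identifiers of the table, so the build used for these values is not given in the sources used here. The counter, its strand setting, the annotation and the normalization tool are not given in the sources used here either. Reads of overlapping genes and of near-identical copies could not be told apart.

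The deposited table holds 11588 genes in 6 columns of a normalized signal, 1 column per library. Within each column 100% of the values were whole multiples of the smallest value above 0 (tolerance 0.001 of a read), so the reads per gene could be recovered. The steps equalled the reciprocals of the size factors that the median-of-ratios method gives on those reads, so the deposited signal is the read count divided by such a size factor. Recovered totals ran from 16127301 to 21023893 reads per library, and a gene near the smallest value rested on single reads. Size factors were 0.904, 0.713 and 0.610 in controls and 1.19, 1.37 and 1.62 with tunicamycin. Differences between every 2 libraries exceeded sampling noise, with a chi-square per gene over 20 in each pair.

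Because the values are normalized, limma (3.58.1, in R 4.3.3) with a mean-variance trend was used on log2(value + 1). The plan had set this test for normalized values and edgeR with TMM factors for raw counts. Genes needed a value of at least 1 in at least 3 libraries, which left 11406, with 182 left out. Groups were compared with no covariate, p-values were adjusted by Benjamini-Hochberg over all genes tested, and the threshold was 0.05. Folds are on the log2(value + 1) scale, which understates the change of low genes, and compare means of log values, so they differ from the ratio of the printed means. Levels are means ± SD of normalized reads over 3 libraries. On simulated reads drawn from these libraries' means, 93% of 4-fold and 21% of 2-fold changes were recovered, with 4 false calls among 11228 unchanged genes. The simulation changed only 100 genes by each fold, whereas 38.4% of tested genes were called here. The adjustment is stricter where few genes change, so these rates do not carry over to the real calls.

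Gene names came from the reference table of assembly ASM15095v2. Table identifiers of the form Phatr3_J followed by a number were matched to locus tags with the same number. This matched 8912 genes, of which 559 had a symbol, and 165 symbols of the reference, among them BiP and several ER-associated degradation genes, met no gene of the table and were not analysed here. The match rests on the number alone. Under it the light-harvesting genes sat at a median percentile of 98.6 by control level. The reference served for symbols, gene lengths and gene order.

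Before the data were examined, 24 gene lists were fixed as patterns on names. The reference gives symbols without product names, so only 4 of them held 5 or more tested genes. After the identifiers were seen and before any test was run, 28 further lists were written from symbols, of which 24 could be tested. Lists were tested with camera at a preset correlation of 0.01 and adjusted within each of the 2 sets of lists. No list call held with a correlation estimated per list. The rule for the genes named was set beforehand: from each of the 5 ER lists fixed beforehand the 3 members with the smallest adjusted p, from every other list described, the further ones included, 2 to 4 by the same order, and the largest changes. The last were the 8 largest rises and 8 largest falls with a symbol, in place of the product name that the rule first asked for, and the 2 largest each way of any gene, among called genes with groups that did not overlap and a mean of at least 10. Of the genes the rule requires, 1 is not reported here. Genes named beyond this were chosen after their values were seen and are marked so.

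Settings fixed beforehand for comparison were quantile normalization, centring on the median gene, no filter, a filter at 10, limma without trend, pseudocounts of 0.1 and 10, a 2-fold threshold, DESeq2 (1.42.0) on the recovered reads, the replicate number as a block, leaving out each library, and 2 other list tests. Added after seeing the data were edgeR (4.0.16) on the recovered reads with TMM, with RLE factors and with library size only, voom with TMM, and list tests after a loess trend of fold change on level was taken off. Enrichment of product-name terms, planned at first, was left out for want of product names.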

Results

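Transcript levels were measured in the pennate diatom Phaeodactylum tricornutum, a marine unicellular alga whose plastid arose from a red alga. Wild-type cells grew in f/2 medium, an enriched seawater medium, at 22 °C under light for 24 h per day. The series compared 3 control libraries with 3 libraries from cells given 0.3 µg/ml tunicamycin, all labelled with a time of 24 h. Tunicamycin blocks the first step in building the sugar chain for N-glycosylation, so that glycoproteins misfold in the endoplasmic reticulum (ER), and the study asked how ER quality control and ER-associated degradation respond to it. The values were read counts per gene divided by a size factor per library, called normalized reads here, for 11588 genes. The control libraries held 18494572, 18144097 and 16127301 reads and the tunicamycin libraries 17189634, 18369700 and 21023893. No label says that the replicates were separate cultures, so p-values measure only the spread between these samples.

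The 2 groups lay apart in the first principal component of log2 levels, which held 64.4% of the variance. Pearson correlations of log2 levels across genes were 0.988 to 0.991 between tunicamycin libraries, 0.942 to 0.980 between control libraries and 0.929 to 0.944 between groups. Control library 1 stood apart from control libraries 2 and 3 in the second component, which held 23.9% of the variance.

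**Figure D1:**
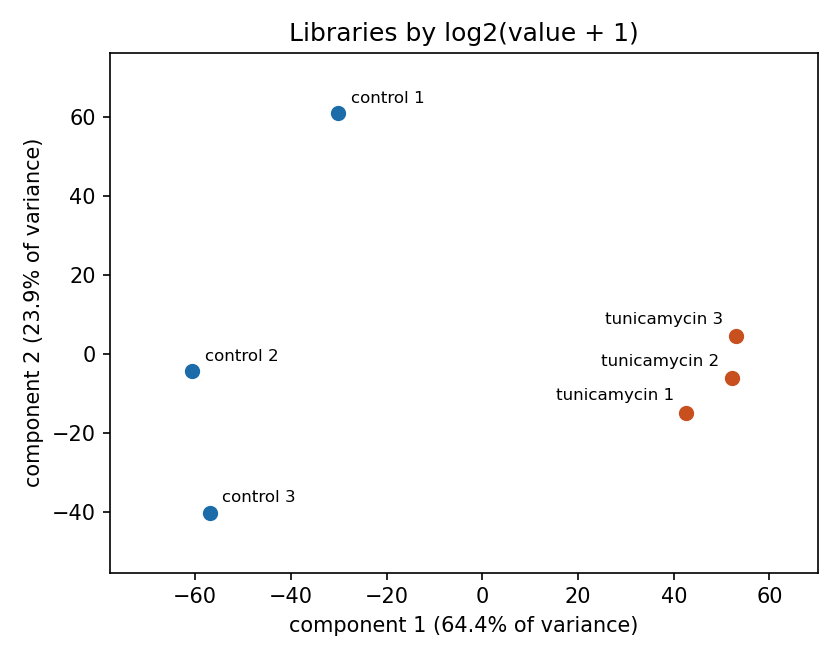
Positions of the 6 libraries on the first 2 principal components of log2(value + 1), with each axis giving its percent of the variance and each point standing for 1 library. The 3 tunicamycin libraries sit close together at the right, and control library 1 lies away from control libraries 2 and 3 along component 2.

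Tunicamycin was followed by rises in small heat shock proteins and falls in most light-harvesting genes, 2 photosystem II genes and 6 of 11 fatty acid synthesis genes. Of 11406 genes tested, 2098 were higher and 2285 lower with tunicamycin, 38.4% of the genes (limma with trend, Benjamini-Hochberg adjusted p below 0.05). At least 2-fold changes made up 1267 of the higher and 1234 of the lower calls, and at least 4-fold changes 201 and 172. In 6034 genes (52.9%, against 10% by chance for 3 against 3) the groups did not overlap. The 559 tested genes with a symbol gave 95 higher and 144 lower calls. A quasi-likelihood test of the recovered whole reads in edgeR, with TMM factors, called 4514 genes. Leaving out 1 library changed the count of called genes to 6735 without control library 1, 2574 without control library 2 and 4640 without control library 3. It was 2568, 2088 and 2199 without tunicamycin libraries 1, 2 and 3.

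The direction of the calls was tied to the size factors and to the level of each gene. The 100 most abundant genes took 26.3% ± 3.40 of the reads in controls and 17.2% ± 1.30 with tunicamycin (SD, n = 3), and the ratio of the upper to the lower quartile of levels was 12.8 ± 1.30 against 7.11 ± 0.352. With reads scaled to library size only, the median gene shifted by 0.78 on the log2 scale and the calls became 5743 higher and 544 lower (edgeR). All changes given here are relative to the size factors, under which the median tested gene changed by 0.02. The median log2 fold change fell from 0.77 in bin 2 to -0.95 in bin 10 when genes were put into 10 equal bins from the scarcest to the most abundant.

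**Figure D2:**
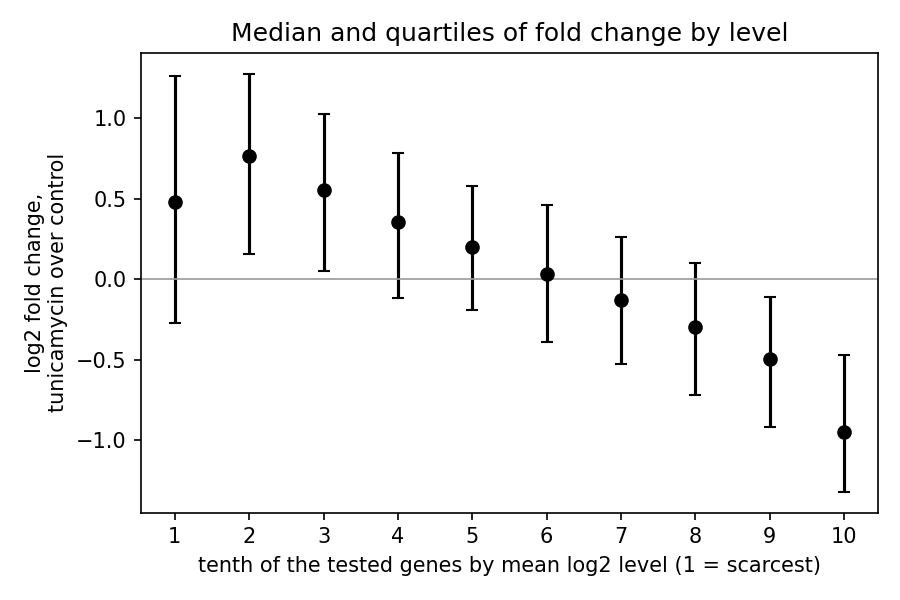
Median log2 fold change of tunicamycin over control (points) with its quartiles (bars) in each of 10 equal bins of the 11406 tested genes, from the scarcest (1) to the most abundant (10). The medians lie between 0.48 and 0.77 in the 3 scarcest bins and at -0.95 in the most abundant.

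Small heat shock proteins, chaperones that hold unfolded proteins, gave the largest rises among genes with a symbol. HSP20C (Phatr3_J36981) rose 23.5-fold, from 159 ± 41.6 to 3796 ± 1054 normalized reads (SD, n = 3; limma adjusted p = 0.00016). HSP20A (Phatr3_J35158) rose 20.2-fold, from 1717 ± 1117 to 29608 ± 10127 (adjusted p = 0.00192), a log2 fold change of 4.34 that was 3.65 without control library 1. HSP70B, an Hsp70 family chaperone, rose 1.73-fold (log2 0.79 ± 0.20 SE, adjusted p = 0.0188). These were the 3 genes called among 11 cytosolic and organellar chaperones, and also the 3 called when adjusted over the list alone. Under quantile normalization 8 of the 11 were called higher (camera adjusted p = 5.74e-06), and with library size only 9. The list test with a preset correlation (camera) gave an adjusted p of 0.0427, and an adjusted p = 0.389 with an estimated correlation. The list was no longer called without control library 1 (adjusted p = 0.141) or tunicamycin library 1 (adjusted p = 0.0650). A wider list of 14 heat shock proteins and chaperonins held 1 more called gene, the chaperonin CPN60_1 (1.57-fold higher, log2 0.65 ± 0.15 SE), and was not called as a list (adjusted p = 0.122, and adjusted p = 0.589 with an estimated correlation). It was called under quantile normalization (5.27e-06, 10 of 14 higher), with DESeq2 (0.0371), with library size only (0.0130), with fry (0.0135) and once the trend with level was taken off (7.79e-09). Leaving out control library 2 or tunicamycin library 2 or 3 ended the calls of HSP70B and CPN60_1 (adjusted p 0.0529 to 0.0896), as did leaving out tunicamycin library 1 for CPN60_1 (0.0703). The log2 fold changes stayed at 0.69 to 0.81 and 0.61 to 0.70 there. Under quantile normalization those of CPN60_1 and HSP20A were 1.89 and 5.20.

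Of the ER pathways named in the study's title, few members could be matched to a gene symbol, and 1 of the 4 matched host components of ER-associated degradation was called. The ER-resident chaperone BiP, the derlin hDer1-1 and the ATPase hCdc48 were not analysed here. The ER membrane ubiquitin ligase hHrd1 (Phatr3_J49801) was 1.42-fold higher, from 673 ± 117 to 944 ± 2.96 normalized reads (SD, n = 3; limma adjusted p = 0.0475), and the other 3 did not pass. DER1 was at 13.9 ± 5.99 in controls and 7.36 ± 3.29 with tunicamycin (adjusted p = 0.239), a low level at which this difference did not pass. The N-glycan-removing enzyme hPng1 was at 874 ± 103 and 1077 ± 14.7 (adjusted p = 0.138), and was called higher under quantile normalization (adjusted p = 0.0212) and with library size only (adjusted p = 0.000871). Under quantile normalization (log2 0.68, limma adjusted p = 0.0150) and with library size only (log2 1.32, edgeR adjusted p = 0.000727) hHrd1 stayed called higher. The call of hHrd1 ended in limma without trend or with log2 values centred on the median gene. It also ended without control library 2 or tunicamycin library 1, 2 or 3 (adjusted p 0.132 to 0.146).

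In glycosylation itself, 2 of 7 genes for sugar nucleotides and glycosyl transfer were higher and none was lower, and the list was not called (camera adjusted p = 0.669). With library size only 6 were higher and none lower, and with DESeq2 2 were higher and 1 lower. GALE1, the UDP-glucose 4-epimerase, rose 2.48-fold (log2 1.31 ± 0.23 SE, limma adjusted p = 0.00518). GFA1, which makes the amino sugar that feeds UDP-N-acetylglucosamine, the donor that tunicamycin mimics, rose 1.48-fold (log2 0.57 ± 0.15 SE, adjusted p = 0.0224). The Alpha--fucosyltransferase gene, the only matched member of the N-glycosylation list, gave a log2 fold change of 0.70 ± 0.29 SE (adjusted p = 0.0932), and passed with library size only (adjusted p = 0.0162) and without control library 1 (adjusted p = 0.000557). GFA1 was not called without control library 2 or tunicamycin library 1, 2 or 3 (adjusted p 0.0672 to 0.101).

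The direction of genes for transport between ER and Golgi depended on the scaling. Of 5 matched genes for ER-Golgi vesicle transport, Arf1, a small GTPase of coat assembly, was called lower (log2 -0.48 ± 0.16 SE, limma adjusted p = 0.0481), but was called higher under quantile normalization (log2 0.66, adjusted p = 0.0200) and was higher, without passing, under scaling to library size only (log2 0.33). Its call was lost without control library 2 or 3 or tunicamycin library 1, 2 or 3 (adjusted p 0.0785 to 0.193), and 0 of the 5 were called when adjusted over the list alone. The coat GTPases Sar1a and Sar1B gave log2 fold changes of -0.26 ± 0.14 and -0.32 ± 0.24 (SE), and Sar1B was called lower without control library 1 (adjusted p = 0.00619). Both were higher with library size only (log2 0.54 and 0.48). The list test did not call this list (camera adjusted p = 0.395). In a wider list of 15 genes for ER entry and ER-Golgi transport, SLY1, a regulator of vesicle fusion, was also called, 1.47-fold higher (adjusted p = 0.0301), and the list was not called (adjusted p = 0.669). It was called in the upward direction under quantile normalization (adjusted p = 0.0117, 8 higher and 0 lower) and once the trend with level was taken off (0.0179), and with library size only 10 of the 15 were higher and 0 lower. The call of SLY1 ended without control library 2 or tunicamycin library 1, 2 or 3 (adjusted p 0.0933 to 0.122). Among 25 genes of post-Golgi and endosomal traffic, 3 were higher and 4 lower (camera adjusted p = 0.669), against 8 and 2 under quantile normalization and 17 and 1 with library size only. AP3mu, a subunit of the AP-3 adaptor of vesicle coats, rose 4.04-fold from 21.7 ± 8.71 normalized reads, VPS45 rose 2.18-fold, and Sec4 was 1.86-fold lower, although higher, without passing, under quantile normalization (log2 0.11) and not called with library size only (log2 -0.09, adjusted p = 0.666).

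None of 8 subunits of the regulatory particle of the proteasome, the protease complex that degrades ubiquitin-tagged proteins, passed the threshold in limma (camera adjusted p = 0.669). Under quantile normalization 1 of the 8 was called higher, and with library size only 6 of the 8. RPN6 gave a log2 fold change of -0.28 ± 0.14 SE and RPN9 of -0.40 ± 0.25, against 0.54 and 0.43 with library size only. RPN9 was called lower without control library 1 (adjusted p = 0.0200). Of 18 genes for ubiquitin, SUMO and cullin ligases, 3 were higher and 7 lower (camera adjusted p = 0.349), against 3 and 1 under quantile normalization and 9 and 1 with library size only. UBC2, a ubiquitin-conjugating enzyme, was 2.60-fold lower and UBI3, a ubiquitin precursor, 2.33-fold lower (limma adjusted p = 0.00148 and 0.0017), while CUL1_2, a cullin scaffold, was 1.96-fold higher (adjusted p = 0.00358). UBC2 and UBI3 were not called under quantile normalization (adjusted p = 0.0950 and 0.308), nor UBI3 with library size only (0.0674).

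**Figure D3:**
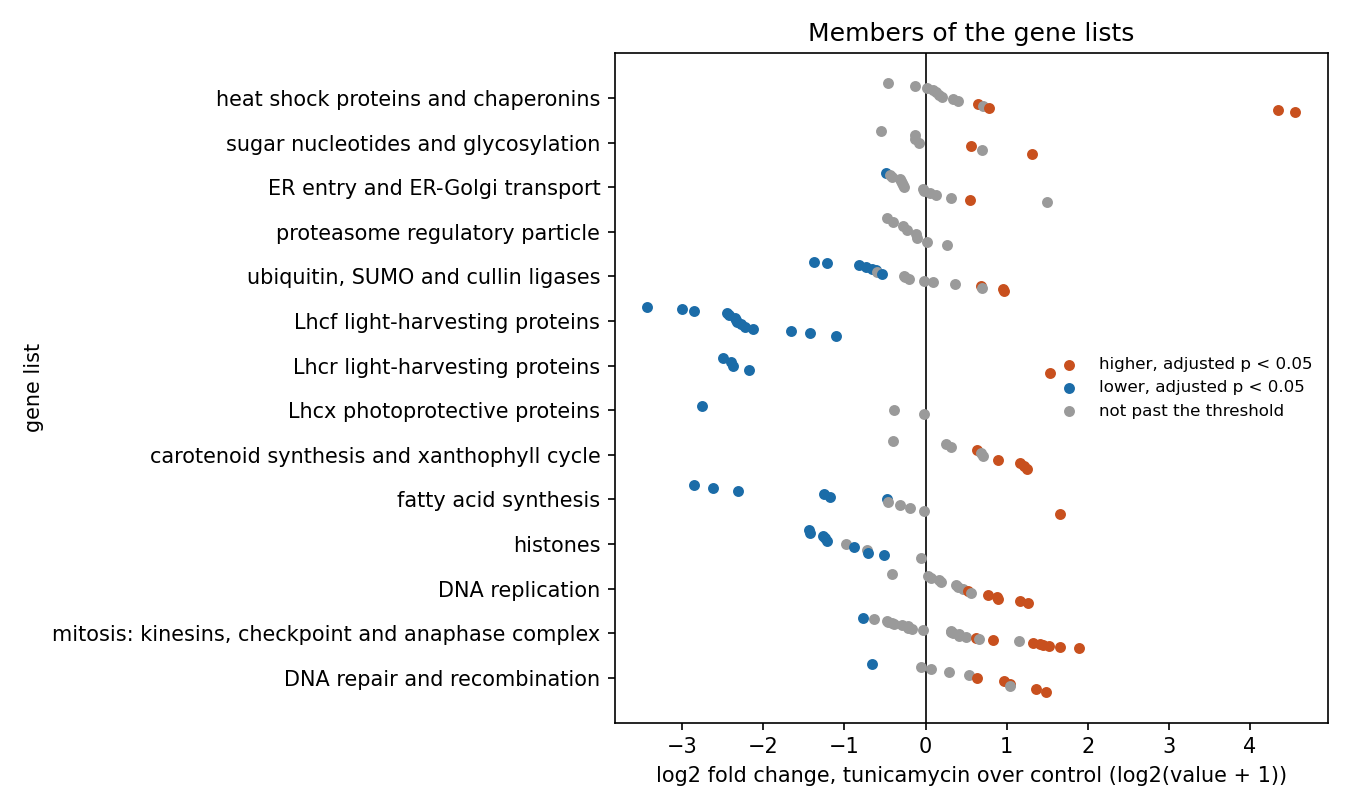
Log2 fold change of tunicamycin over control for each tested member (points) of 14 gene lists (rows), colored by whether limma's adjusted p was below 0.05. All 14 Lhcf points lie left of 0, and HSP20A and HSP20C lie alone beyond 4 at the right.

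Light-harvesting genes, which encode the fucoxanthin and chlorophyll proteins of the diatom antenna, fell together. Of 22 measured members, of 35 in the reference, 19 were lower and 1 higher, with a median log2 fold change of -2.33, which was -1.21 under quantile normalization and -1.52 with library size only. The counts were the same when adjusted over the list alone (camera adjusted p = 2.68e-12, and adjusted p = 0.148 with an estimated correlation). The family took 2.74% ± 0.101 of the reads in controls and 0.972% ± 0.0474 with tunicamycin (SD, n = 3). Lhcf5 (Phatr3_J30648) fell 10.8-fold, from 123657 ± 16551 to 11440 ± 1167 normalized reads, and Lhcf3 (Phatr3_J50705) fell 8.01-fold, from 20243 ± 2257 to 2521 ± 206 (limma adjusted p = 0.00016 and 0.000138). All 14 measured Lhcf genes, of 17 in the reference, were lower (camera adjusted p = 4.33e-11, and adjusted p = 0.416 with an estimated correlation), Lhcf7 by 5.02-fold and Lhcf8 by 7.23-fold. Of 5 measured Lhcr genes, of 14 in the reference, 4 were lower (camera adjusted p = 0.0186, and adjusted p = 0.589 with an estimated correlation), Lhcr11 by 5.64-fold and Lhcr4 by 5.19-fold. Lhcr8, chosen after its values were seen, was 2.89-fold higher (limma adjusted p = 0.0137), but was not called under quantile normalization (adjusted p = 0.0672) or without tunicamycin library 1 (0.0596) or 2 (0.0519). Lhcx1, a photoprotective member, fell 6.75-fold, from 20719 ± 7683 to 2934 ± 585 (limma adjusted p = 0.00138), while the other 2 measured Lhcx genes, of 4 in the reference, did not pass, among them Lhcx4 (log2 -0.38 ± 0.38 SE, and 0.26 with library size only). With library size only, 18 members were still lower and 1 higher, and under quantile normalization 17 were lower and none higher. Lhcf5, Lhcf3, Lhcx1 and Lhcr11 had smaller log2 fold changes there, of -2.21, -2.09, -1.82 and -1.38. These genes sat at a median percentile of 98.6 by control level, where most genes were lower, and reads of near-identical copies can be counted for the wrong member.

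The photosystem II genes PsbO and PsbM, the only 2 matched, were lower as well. PsbO (Phatr3_J20331), which shields the oxygen-evolving site, fell 3.91-fold from 70423 ± 8543 to 17950 ± 1221 normalized reads, and PsbM (Phatr3_J55057) fell 4.75-fold (SD, n = 3; limma adjusted p = 0.000841 and 0.000332). Their log2 fold changes of -1.97 and -2.25 were -0.60 and -1.09 under quantile normalization and -1.15 and -1.43 with library size only. The other gene that the photosystem pattern took up, PSAT, shares the start of its symbol with photosystem I genes but encodes phosphoserine aminotransferase, and was at 1826 ± 148 and 1986 ± 168. PSAT was called higher under quantile normalization (adjusted p = 0.0190) and with library size only (adjusted p = 0.00341). Tpt3 (Phatr3_J54017), a triose phosphate transporter, fell 7.60-fold and GapC1 (Phatr3_J22122), a glyceraldehyde-3-phosphate dehydrogenase, 7.02-fold, from 48484 ± 5405 to 6948 ± 1228 (adjusted p = 0.00017 and 0.000219). GapC1 went from a log2 fold change of -2.81 to -1.57 under quantile normalization. LHL1 (Phatr3_J17326) fell 6.57-fold, from 158 ± 99.5 to 20.3 ± 2.65 (adjusted p = 0.00427).

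**Figure D4:**
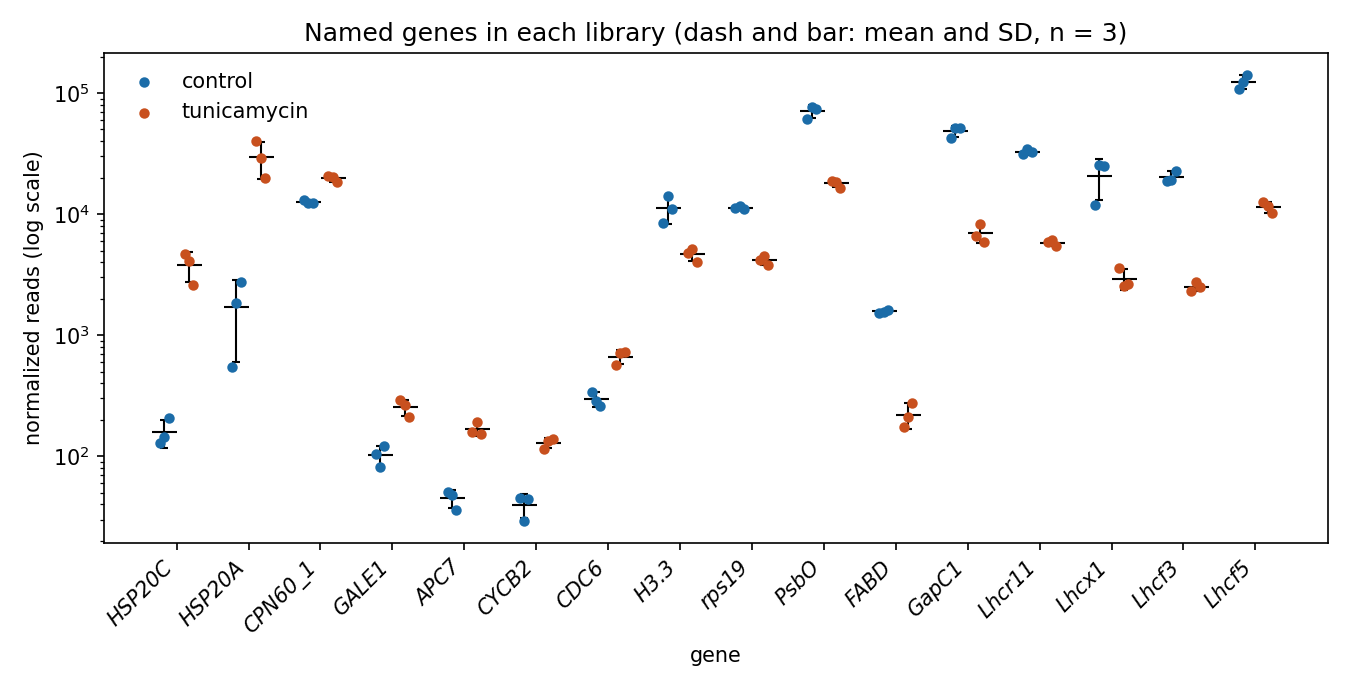
Normalized reads (log scale) of 16 named genes in each library, with control libraries in blue, tunicamycin libraries in orange, and a dash and bar for the mean and SD of 3 libraries. Mean normalized reads of HSP20A rise from 1717 to 29608, and Lhcf5 falls from 123657 to 11440.

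Fatty acid synthesis genes were mostly lower. Of 11 tested genes, 6 were lower and 1 higher (camera adjusted p = 0.0132, and adjusted p = 0.416 with an estimated correlation). The median log2 fold change was -0.48, at percentile 22.8 among 10000 random lists matched on level. The typical member thus fell about as genes of like level did. The list stayed called once the trend with level was taken off (camera adjusted p = 0.00302). FABD (Phatr3_J37652), the malonyl transferase that starts chain growth, fell 7.22-fold, from 1572 ± 37.6 to 221 ± 52.5 normalized reads (SD, n = 3; limma adjusted p = 0.000201). The condensing enzymes FABFa and FABB fell 6.14-fold and 4.98-fold, whereas FABFb, chosen after its values were seen, was 3.14-fold higher (log2 1.65, and 1.03 under quantile normalization) from 52.8 ± 25.5 (adjusted p = 0.00838). The list was not called under quantile normalization (adjusted p = 0.147), and with library size only 3 genes were higher and 3 lower. All 4 matched ribosomal protein genes were lower, too few for a list test: rps19 (log2 -1.44), rpl2 (-1.28), rpl14 (-1.18) and rpl20 (-0.58). Only rps19 was called under quantile normalization (log2 -0.53). With library size only, rps19 alone stayed called lower and rpl20 was higher (log2 0.23). The call of rpl20 also ended without control library 2 or tunicamycin library 1, 2 or 3 (adjusted p 0.0564 to 0.113).

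Most histone genes were lower, and 6 of 15 genes for DNA replication were higher. Of 11 histone genes, 8 were lower and none higher, with a median log2 fold change of -0.98 (camera adjusted p = 0.00794, and adjusted p = 0.606 with an estimated correlation). H2A-m2, H3.3 and H2B-1a fell 2.40-fold, 2.36-fold and 2.71-fold, and H3.3 went from 11195 ± 2845 to 4659 ± 582 normalized reads (SD, n = 3), a change not called under quantile normalization (limma adjusted p = 0.204). Under scaling to library size only, 0 of the 11 were called and the median was -0.23, and fry, a test of whether the list moved on balance, gave an adjusted p of 0.0503. Of 15 replication genes, 6 were higher and none lower, with a median log2 fold change of 0.46 (camera adjusted p = 0.0373, and adjusted p = 0.416 with an estimated correlation). The counts were 13 and 0 (median 1.22) with library size only and 3 and 0 under quantile normalization. Among 10000 random lists matched on level, the median of 0.46 lay at percentile 95.9, inside their 95% range of -0.303 to 0.510. CDC6, which loads the replicative helicase, rose 2.25-fold and the helicase subunit MCM5 1.86-fold (limma adjusted p = 0.00324 and 0.0193). MCM5 was not called without tunicamycin library 2 or 3 (adjusted p = 0.0909 and 0.0769) or under quantile normalization (0.0715). The replication list was not called without control library 2 (adjusted p = 0.0503) or tunicamycin library 2 (0.0773), or in any of the 5 count tests of the recovered reads (0.0580 to 0.0866), or once the trend with level was taken off (0.0954). Over the 10 replication and cell cycle genes of the list fixed beforehand, 4 were higher and 1 lower, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.130), against 8 and 1 with library size only and 1 and 1 under quantile normalization. CDKC2 fell 2.49-fold (log2 -1.32, and -0.51 under quantile normalization) and CDKD1 rose 2.33-fold. CDKD1 was not called without control library 2 or tunicamycin library 1 or 2 (adjusted p 0.0533 to 0.0722) or under quantile normalization (0.193).

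More genes of mitosis and DNA repair were called higher than lower. Neither list was called, but under quantile normalization both were (camera adjusted p = 0.0309), and the mitosis list was once the trend with level was taken off (0.0483). Scarcer genes tended to rise, and among 10000 random lists matched on level the mitosis median (0.336) lay at percentile 97.3. That was inside their 95% range of -0.332 to 0.340. The DNA repair median (0.632) lay at percentile 99.3, above the 95% range of its random lists (-0.438 to 0.507). Of 27 kinesins, checkpoint and anaphase complex genes, 8 were higher and 1 lower (camera adjusted p = 0.135), against 18 and 0 with library size only. The anaphase-promoting complex, the ubiquitin ligase that ends mitosis, gave its subunits APC7 (3.71-fold), APC8 (3.15-fold), APC6 (2.87-fold) and APC2 (2.72-fold) among them, with limma adjusted p of 0.00153 to 0.00586. CYCB2, a B-type cyclin, rose 3.25-fold from 39.7 ± 8.89 normalized reads (SD, n = 3), and CYCP6 was lower (log2 -1.32 ± 0.14 SE, and -0.52 under quantile normalization). Of 21 cyclins and cyclin-dependent kinases, 7 were higher and 3 lower (camera adjusted p = 0.558), against 15 and 3 with library size only. Of 11 DNA repair genes, 5 were higher and 1 lower (camera adjusted p = 0.0938, and 0.0233 without control library 1), against 7 and 0 with library size only. XPF, a nucleotide excision repair nuclease, rose 1.96-fold. Carotenoid genes were called as a list, with 5 of 10 higher and none lower (camera adjusted p = 0.0373, and adjusted p = 0.416 with an estimated correlation). The carotenoid isomerase CRTISO1 rose 2.33-fold and the zeaxanthin epoxidase ZEP1 2.37-fold. The carotenoid list was not called without control library 2 (adjusted p = 0.0503) or tunicamycin library 3 (0.0531), in 4 of the 5 count tests (0.0786 to 0.0838), or once the trend with level was taken off (0.0632). ZEP1 was not called without control library 2 or tunicamycin library 1, 2 or 3 (adjusted p 0.0505 to 0.0573).

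Among the other genes with the largest changes, CsdB, a cysteine desulfurase, rose 3.97-fold, from 38.7 ± 10.3 to 153 ± 13.6 normalized reads (SD, n = 3; limma adjusted p = 0.00202). PHOD, an alkaline phosphatase, rose 3.54-fold (adjusted p = 0.0196) and FAO1 3.33-fold (adjusted p = 0.00947). Under quantile normalization the log2 fold changes of AP3mu, CsdB, APC7 and CYCB2 were smaller, at 1.34, 1.37, 1.28 and 1.05. PHOD was not called without control library 2 or tunicamycin library 1, 2 or 3 (adjusted p 0.0512 to 0.0796) or under quantile normalization (adjusted p = 0.135). Genes without a symbol changed further. Phatr3_EG01529 fell 70.4-fold, from 6422 ± 1574 to 91.6 ± 27.5, and Phatr3_J45944 fell 63.3-fold, from 48895 ± 8262 to 773 ± 138 (adjusted p = 7.32e-05 and 4.35e-05). A locus with no symbol, whose identifier is not printed here, rose 45.2-fold, from 10.2 ± 8.08 to 389 ± 98.6 (adjusted p = 0.00164), a log2 fold change of 5.50 that was 4.66 without control library 3.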

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

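The edgeR and voom fits of the recovered reads and the removal of the trend with level were added after seeing the data. Of these, edgeR with TMM was the test planned for raw counts. Quantile normalization, which removes the trend with level, called 3204 genes, and 53.0% of the 4383 called genes kept their call and direction there. The count stayed between 4121 and 5172 with no filter, a filter at 10, other pseudocounts, limma without trend, centring, DESeq2, edgeR with TMM or RLE, and voom. It was 2501 at a threshold of at least 2-fold (1267 higher and 1234 lower), where only the stricter threshold differs. With library size only, 5743 genes were higher and 544 lower, because the size factors differ between the groups. Leaving out 1 library gave 2088 to 6735 called genes, 828 to 3318 higher and 1260 to 3417 lower, fewest without tunicamycin library 2 and most without control library 1. With the replicate number as a block, 2591 genes were called, 1125 higher and 1466 lower. The deviations of same-numbered libraries correlated at -0.41, -0.02 and -0.36, and no library correlated best with its own number. No sign of pairing by number was thus seen, but 3 libraries per group are too few to exclude a shared culture. Of the list tests, 8 were called, against 0 with a correlation estimated per list 13 with fry, which does not compare a list with other genes, 12 under quantile normalization and 10 with the trend with level taken off. Lists not called in limma but called there include heat shock proteins and mitosis (all 3), DNA repair (fry and quantile normalization) and ER entry and ER-Golgi transport (the last 2). The lowest correlation between replicates was 0.942 by Pearson and 0.939 by Spearman.

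Of 72 called genes named in the text, 67 kept their direction in every alternative and 44 also their call. Reversed under quantile normalization were Arf1 (log2 0.66), Sar1a (0.16) and Sec4 (0.11). Reversed with library size only were Arf1 (0.33), Sar1a (0.54), Sar1B (0.48), rpl20 (0.23), GLRX1 (0.20), FRE1 (0.28), RPN6 (0.54), RPN9 (0.43) and Lhcx4 (0.26). The cause was not tested for single genes. Few reads stood behind genes such as DER1, with normalized reads near 10. Whether depth, spread or the number of libraries limited such genes was not tested. Enrichment of product-name terms with its alternatives, the list of organelle-encoded genes and the list of ER retention signals were not run, since no product names, genome or organelle map was used here.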

Other observations

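All tests of explanations were set before their results were seen, except 3: the tests of summed light-harvesting counts, of the added background among abundant genes and of the range of control library 1 were chosen afterwards. Gene groups not described so far moved in parts. The COP9 signalosome, a regulator of cullin ligases, had 2 of 7 genes higher and 2 lower (camera adjusted p = 0.669). CSN1 rose 3.19-fold and CSN3 1.84-fold, while CSN8 was 3.69-fold and CSN6 1.91-fold lower. CSN6 and CSN3 were not called under quantile normalization (limma adjusted p = 0.155 and 0.0585), nor CSN6 with library size only (0.565), and CSN3 was not called without tunicamycin library 1 (0.0548) or 2 (0.0663). Of 11 redox genes, 4 were lower and none higher (camera adjusted p = 0.0852, and 0.0233 without control library 1), while with library size only 4 were higher and 2 lower. SOD1, a superoxide dismutase, fell 4.21-fold (log2 -2.07, and -1.38 under quantile normalization) and the glutaredoxin GLRX1 1.53-fold. GLRX1 was higher with library size only (log2 0.20) and was not called without control library 2 or tunicamycin library 1, 2 or 3 (adjusted p 0.0614 to 0.104).

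Carbon metabolism held changes in both directions. Of 14 glycolysis genes, 2 were higher and 3 lower (camera adjusted p = 0.669). The counts were 5 and 2 under quantile normalization and 7 and 1 with library size only. GapC1 was 7.02-fold lower and the pyruvate kinase PK4a 2.93-fold higher. The list was written from symbols, which do not say where in the cell an enzyme works. Whether GapC1 belongs to glycolysis or to the Calvin cycle was not examined here. Of 6 photorespiration genes, 1 was higher and 2 lower (camera adjusted p = 0.669), against 2 and 1 under quantile normalization and 3 and 1 with library size only. Of 4 Calvin cycle genes, too few for a list test, 1 was higher and 1 lower: Rpe, a pentose phosphate epimerase, fell 5.93-fold and PGK, phosphoglycerate kinase, was 1.37-fold higher. PGK was not called without control library 2 or tunicamycin library 1, 2 or 3 (limma adjusted p 0.115 to 0.136). GDCH, the H protein of glycine decarboxylase, fell 2.32-fold and GOX, glycolate oxidase, rose 3.21-fold. GOX was not called without control library 2 or tunicamycin library 2 or 3 (limma adjusted p 0.0745 to 0.0805). Of 9 genes for iron starvation and ferric reduction, 1 was higher and 2 lower (camera adjusted p = 0.482), against 2 and 0 of 8 with library size only. ISIP2A, an iron uptake protein, fell 2.07-fold but was not called with library size only (adjusted p = 0.237), FRE1 was 1.43-fold lower, and ISIP1 was 2.20-fold higher from 25.6 ± 10.4 normalized reads (SD, n = 3). FRE1 turned higher with library size only (log2 0.28), and FRE1 and ISIP1 were not called under quantile normalization (adjusted p = 0.620 and 0.346). FRE1 and ISIP1 were not called without control library 2 or tunicamycin library 1, 2 or 3 (adjusted p 0.0822 to 0.128), nor ISIP1 without control library 3 (0.0615).

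The fall of abundant genes and rise of scarce ones was the widest pattern, with a Spearman's rho of -0.516 between level and log2 fold change across genes, which are not independent replicates. It stayed at -0.518 after all libraries were thinned to the same number of reads. Between control library 1 and tunicamycin library 2, which hold 18494572 and 18369700 reads, rho was -0.401. Between control library 2, with 18144097 reads, and tunicamycin library 2 it was -0.522. These values argue against depth as the cause of the pattern. A few dominant genes would shift all other genes alike and leave their ranks in place, so the -0.508 without the 100 most abundant genes decides nothing. An added background of reads in the tunicamycin libraries could give a difference of at most 0.144 between bins 6 and 10 of genes by level, and the difference was 0.98 (95% bootstrap interval 0.895 to 1.05), so it does not account for the abundant genes. For the scarcer genes a background cannot be told apart from a rise: reads per kb at the 5th percentile were 1.08 times the rise to be explained, but gene lengths were known for 77.7% of genes, under the 80% needed. A change of the cells' RNA with tunicamycin stays open as a hypothesis, untested beyond the group difference.

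The fall of light-harvesting genes exceeded that trend as matched here: its median lay at percentile 0 among 10000 random lists matched on level. The matching used 20 equal bins, and these genes sat at a median percentile of 98.6 by control level. A steeper trend within the top bin thus stays open. An exchange of reads between near-identical measured copies would leave their sum in place. But the highest tunicamycin library held 0.250 times the summed normalized reads of the lowest control library. The sum covers 22 of the 35 members in the reference, so an exchange with unmatched copies stays open. The trend with level, as far as the 20 bins resolve it, and an exchange among measured copies are argued against by these values. A lower transcript level of the antenna genes relative to genes of like abundance may thus be biological, as a hypothesis found and tested on the same data. Whether it follows from N-glycosylation, ER stress or slower growth was not tested.

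Control library 1 stood apart from control libraries 2 and 3, with 93 genes at least 4-fold higher and 174 at least 4-fold lower than their mean. It also shared part of the trend with level: rho was -0.214 and -0.167 in control 1 against controls 2 and 3, and -0.000499 between those. An admixture of tunicamycin-treated material as the whole cause would place control library 1 between the groups. On the first principal component it did lie between, at -30.1. Control libraries 2 and 3 were at -60.7 and -56.9 there, and the tunicamycin libraries at 42.6 to 53.0. But 68.9% of the genes at least 4-fold apart lay outside the range of the other 5 libraries, against 47.5% of all tested genes. Picking genes by their distance from control libraries 2 and 3 itself favours values outside that range. The contrast between the 2 shares is thus partly set by the selection. An admixed share of 4.44% (95% bootstrap interval 2.22 to 8.26) was estimated from 148 genes raised at least 4-fold, so a small admixture stays open. Depth is argued against as well, since the gap in correlation to the other controls was 0.0273 after thinning. A different state of that culture or its handling may be the source, and no label bears on it.

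As a hypothesis of co-regulation, neighbouring genes may change together. Over 8073 pairs of adjacent genes the log2 fold changes correlated at 0.0919 (0.0818 after the trend with level was taken off), above the highest of 10000 shuffles of gene order (0.0459, permutation p = 1e-04, the smallest they can give). The relation is weak: of 1331 pairs with both genes called, 770 (57.9%) went the same way. The shuffles bear on gene order alone. Reads of overlapping genes and near-identical copies could not be told apart, so shared reads stay open for adjacent genes in general. Among the pairs are Lhcf1 to Lhcf4, which lie side by side and are near-identical copies.

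Splits of the 6 libraries into 3 and 3 are too few, at 10, for a share under 0.05: the real split called 4383 genes, 1 of the 10 reached that many, and the highest other split called 0. At an unadjusted p below 0.05 limma gave 5578 genes for the real split.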
